A study of Mus musculus with 18 samples.

How the data were processed

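RNA sequencing was performed on mouse primary chondrocytes, the cells of cartilage, in 18 libraries that fall into 6 groups of 3. Cells were kept at 21% oxygen (normoxia) or 1% oxygen (hypoxia) and sampled at 0 h untreated, at 12 h untreated, or at 12 h after addition of interleukin-6 (IL-6), a cytokine, at 100 ng/ml. The protocol text mentions IL-6 or IL-6R, and the sample labels name IL-6 alone as the treatment, so whether the receptor was also added is open. Per the labels' protocols, ribosomal RNA was depleted before library construction and single-end reads of 50 bp were sequenced. Reads were aligned to the mm10 mouse genome with TopHat2 and counted with HTSeq, and differential expression was tested with DESeq2, per the submitters' processing notes, with versions not given in the sources used here.

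The deposited table holds raw read counts, with no normalization by the authors, for 63244 UCSC transcript identifiers in each of the 18 libraries. Of these identifiers, 30721 had at least 1 count. The table pairs no identifier with a gene symbol, and the gene tables used here carry no UCSC identifiers, so no gene is named. For the same reason the 38 gene lists, the cell type markers and the gene symbols fixed before the data were examined are not analysed here. Gene length and GC content were not used here either. Each identifier is a transcript, so several identifiers may belong to 1 gene and a number of identifiers is not a number of genes. The 5 HTSeq summary rows name no identifier and were left out of library totals and tests. Among uniquely aligned reads, the ambiguous row held a mean of 46.5% ± 2.71 (SD, n = 18) and the row for reads outside annotated features 17.9% ± 4.26 (SD, n = 18), leaving 35.7% ± 1.90 (SD, n = 18) assigned to a single identifier. Transcripts that overlap others on the genome are therefore measured from only part of their reads, and values of such identifiers are uncertain.

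Assigned counts per library ranged from 3088280 to 10241162. A count of 0 in a library allows up to 3 counts, which is 0.293 CPM before TMM scaling in the deepest library and 0.971 CPM in the shallowest, for counting error only. Within groups, library pairs differed far beyond sampling noise, with chi-square per degree of freedom from 15.3 to 149 over identifiers with a summed count of at least 20, so no library was treated as a duplicate. The labels number the replicates 1 to 3 and do not say whether they came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Sequencing lane 3 held 3 libraries of each oxygen condition and lane 6 held 1 of normoxia and 3 of hypoxia, while lanes 2 and 7 held normoxia only and lane 8 hypoxia only, so lane and oxygen are partly confounded. In normoxia, replicate 2 was in lane 3 untreated at 12 h and in lane 6 with IL-6. Replicate 1 there was in lane 3 at 0 h and in lane 2 at 12 h. Lane thus also enters the normoxia IL-6 and time comparisons and both interactions.

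Tests used edgeR 4.0.16 in R 4.3.3. Identifiers were filtered with filterByExpr by group, which kept 13432 identifiers holding 99.5% to 99.7% of each library's counts. Libraries were scaled with TMM, and the robust quasi-likelihood F-test was fitted to all 18 libraries with 1 coefficient per group and no covariate. An identifier was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. There were 9 comparisons: IL-6 in each oxygen condition and its interaction with oxygen, hypoxia against normoxia in each of the 3 treatment states, and 12 h against 0 h in each oxygen condition and its interaction with oxygen. Principal components used the 2000 most variable identifiers on log2 CPM with a prior count of 2. The set test was camera from limma 3.58.1.

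The rule for naming, fixed before the data were examined, took the largest changes in each direction among called identifiers with a mean of at least 5 CPM over the compared libraries and no overlap between the 2 groups. Because identifiers have no gene names, only 2 that rose and 2 that fell are printed in all. For each direction these are the first by the rule for IL-6, in normoxia if any passed and otherwise in hypoxia, and the first for hypoxia at 0 h; they are not the largest changes over all comparisons, and this reduction was made after the data were seen.

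Same-numbered libraries within an oxygen condition deviated together from their group means. Their correlations across identifiers ran from 0.42 to 0.69 in normoxia and from 0.23 to 0.63 in hypoxia. Different-numbered libraries of different groups reached at most 0.04 in normoxia but 0.24 in hypoxia. Each hypoxia number also kept to a single lane, so lane could give that pattern. The numbers were used as pairs for the IL-6 and time comparisons only in the fits with a block, which is less certain in hypoxia. The main counts, from the fit without a covariate, ignore any pairing. Across oxygen conditions same-number correlations ran from -0.13 to 0.02 for replicate 1, from 0.32 to 0.50 for replicate 2 and from 0.10 to 0.49 for replicate 3. The labels carry the same number and prefix in both oxygen conditions without saying what these mark, so pairing across oxygen stays open; the hypoxia comparisons were left unpaired because replicate 1 did not deviate together, and their blocked counts are printed beside them. Values with a replicate block within oxygen are printed beside the unblocked ones. This block was chosen after seeing the data, and its first calls were seen together with the correlations. Alternatives fixed beforehand were DESeq2 size factors (RLE), no filter on low counts, DESeq2 1.42.0, a replicate block, a replicate block with sequencing lane, only the compared groups in the fit, and leaving out each library. Few of the blocks by replicate and lane held both oxygen conditions, and none held both 12 h untreated groups. Their counts for hypoxia against normoxia therefore rest largely on indirect comparisons.

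The tests were run on simulated counts drawn from fitted means, library sizes and dispersions, with 200 of 13432 identifiers changed, 100 by each fold, among those with a mean of at least 20 counts. For the IL-6 and time comparisons the fit behind the simulation held the replicate block within oxygen, which favours the blocked test. For IL-6 in normoxia, 15% of the 2-fold and 76% of the 4-fold changes were recovered without the block, and 80% and 99% with the replicate block within oxygen. For hypoxia at 12 h untreated, 15% and 84% were recovered. For the IL-6 by oxygen interaction, 0% and 43% were recovered without the block and 66% and 98% with it, and for 12 h against 0 h in hypoxia 13% and 78% without and 72% and 98% with it. The false share of calls was 0% without the block in these 3 simulations, and with it 4.28% for IL-6 in normoxia, 6.29% for the IL-6 by oxygen interaction and 2.86% for 12 h against 0 h in hypoxia. For hypoxia at 12 h untreated it was 3.88% with edgeR and 10.8% with DESeq2, and for IL-6 in normoxia it was 0% with DESeq2. The hypoxia simulation drew libraries independently, so its false share does not cover deviations shared by same-numbered libraries.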

Results

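The transcriptomes of mouse primary chondrocytes were measured by RNA sequencing at 21% oxygen and at 1% oxygen, at 0 h and 12 h without treatment and at 12 h with IL-6, with 3 libraries in each of the 6 groups. Assigned counts per library averaged 7098814 ± 2137113 (SD, n = 18) and ranged from 3088280 in hypoxia at 0 h, replicate 3, to 10241162 in hypoxia at 12 h with IL-6, replicate 1. The first principal component held 32.4% of the variance and separated the oxygen conditions, with all 9 normoxia libraries below 0 and all 9 hypoxia libraries above 0. The 3 hypoxia libraries of replicate 3 lay farthest along it, at 33.7 to 50.6, against 9.83 to 13.5 for the other 6 hypoxia libraries. These 3 libraries were also the only ones sequenced in lane 8.

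**Figure D1:**
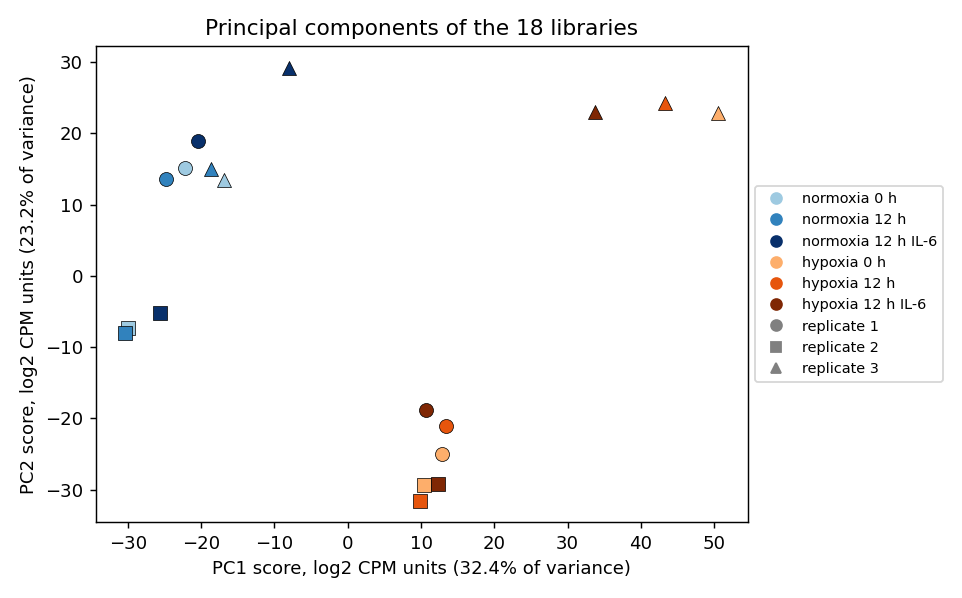
Scores of the 18 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, in log2 CPM units; colour gives the group and marker shape the replicate number. Normoxia libraries lie left of 0 and hypoxia libraries right of 0, with hypoxia replicate 3 at 33.7 to 50.6 on the first component.

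IL-6 raised 27 identifiers in normoxia and lowered none, by edgeR's quasi-likelihood test at adjusted p under 0.05. All 27 rose at least 2-fold and 18 of them at least 4-fold. The identifier ranked first by the rule for naming, uc007oxf.2, was at 0.738 CPM ± 0.270 (SD, n = 3) in untreated cells, from 4 to 10 counts per library. With IL-6 it was at 11.6 CPM ± 2.68 (SD, n = 3), a log2 fold change of 3.91 (SE 0.59, edgeR adjusted p = 0.00405). It was higher in 3 of 3 same-numbered pairs, which the rule fixes by asking for no overlap. The second by the rule, not printed here, rose from 97.1 CPM ± 19.8 (SD, n = 3) to 1438 CPM ± 545 (SD, n = 3). Its log2 fold change was 3.89 (SE 0.34, edgeR adjusted p = 7.14e-06). With the replicate block within oxygen, 398 identifiers were called, 272 higher and 126 lower, of which 132 changed at least 2-fold; leaving out replicate 1 in every group gave 161 (130 higher, 31 lower) and leaving out replicate 2 gave 260. The replicate block fixed beforehand, with 1 term per number across oxygen conditions, gave 99, 85 higher and 14 lower. All 27 identifiers called without the block were also called with it. The fit without a block ignores any pairing by number. It put 414 identifiers at an unadjusted p under 0.05 by edgeR, where 671.6 would be expected by chance. With the replicate block within oxygen there were 1642, so the 27 and the lack of lower calls may understate the response. Without normoxia 12 h untreated replicate 2, 6 identifiers were called and uc007oxf.2 was not among them (adjusted p = 0.0599); without normoxia 12 h untreated replicate 1, 17 were called. With only the compared groups in the fit 16 were called, and DESeq2 called 73, 67 higher and 6 lower.

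In hypoxia, IL-6 raised 52 identifiers and lowered 4, 56 in all, with 48 higher and 4 lower by at least 2-fold. The IL-6 libraries compared here were deeper than the untreated ones, with mean assigned totals of 8043653 and 4861150. The largest rise by the rule for naming was in an identifier not printed here, with a log2 fold change of 4.98 (SE 0.63, edgeR adjusted p = 0.000847). The identifier uc007oxf.2 rose here too, from 1.60 CPM ± 1.08 (SD, n = 3) to 10.9 CPM ± 4.13 (SD, n = 3), a log2 fold change of 2.84 (SE 0.57, edgeR adjusted p = 0.0305). Among those that fell, uc007yuz.2 went from 14.4 CPM ± 5.52 (SD, n = 3) to 2.85 CPM ± 0.331 (SD, n = 3), a log2 fold change of -2.33 (SE 0.40, edgeR adjusted p = 0.00845). It was lower in 3 of 3 same-numbered pairs, which the rule for naming fixes by asking for no overlap. In normoxia the same identifier had a log2 fold change of -1.31 (SE 0.39), which did not pass the test without the block (adjusted p = 0.491) and did with it (adjusted p = 0.0067). With the replicate block within oxygen, 729 identifiers were called for IL-6 in hypoxia, 503 higher and 226 lower, and these included all 56; leaving out replicate 1 in every group gave 198 (165 higher, 33 lower), and the replicate block fixed beforehand gave 169 (141 higher, 28 lower). Leaving out 1 library gave 25 calls without hypoxia 12 h untreated replicate 1, 28 without replicate 2 of that group, and 21 without hypoxia 12 h IL-6 replicate 1. The call of uc007oxf.2 was lost without each of those 3 libraries and without hypoxia 12 h IL-6 replicate 3, at adjusted p from 0.0741 to 0.209, and that of uc007yuz.2 without hypoxia 12 h untreated replicate 1 or hypoxia 12 h IL-6 replicate 1 or 2, at adjusted p from 0.0593 to 0.083. With only the compared groups in the fit, 4 identifiers were called, and neither uc007oxf.2 (adjusted p = 0.242) nor uc007yuz.2 (adjusted p = 0.118) was among them. DESeq2 called 126, and 36 were called without hypoxia replicate 3 in all 3 groups, an alternative chosen after seeing the data.

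The IL-6 responses in the 2 oxygen conditions shared 24 raised identifiers, against 0.105 for independent lists of the same sizes. All 59 identifiers called in either condition had the same sign in both. With the block the shared identifiers were 199 raised and 63 lowered, and 1 was called in opposite directions. Across all 13432 tested identifiers, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.320 and a Spearman correlation of 0.225. Pearson's value was 0.0788 with DESeq2 and 0.0629 with no filter on low counts. Both of those runs took in every identifier with at least 1 count, so these values are not over the same 13432. The covariance over the 13432 was 0.0553, against 0.00218 from the shared deviations of same-numbered libraries. The test of the difference itself, the IL-6 by oxygen interaction, called 0 identifiers by edgeR and 0 by DESeq2, with 167 at an unadjusted p under 0.05 by edgeR, where 671.6 would be expected by chance. With the replicate block within oxygen, 1078 were at an unadjusted p under 0.05 by edgeR, more than the 671.6. The blocked interaction called 6, 4 with a higher and 2 with a lower response in hypoxia, and 0 when replicate 1 was left out in every group or 3 when replicate 2 was. Without replicate 3 it called 4, all higher, of which 2 were among the 6.

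**Figure D2:**
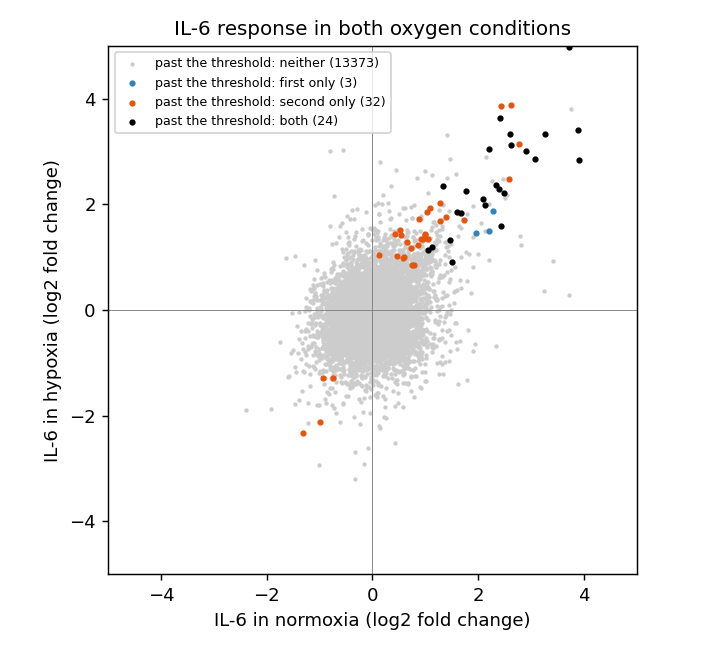
Log2 fold change with IL-6 in normoxia (x axis) and in hypoxia (y axis) for 13432 identifiers, each a point coloured by the comparison in which it passed the test. The 24 identifiers past the threshold in both all lie in the upper right quadrant.

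Without a block, and with the replicate block fixed beforehand, more identifiers passed the test for hypoxia than for IL-6. The block within oxygen gave 729 for IL-6 in hypoxia but leaves no test of hypoxia to set beside it. Oxygen is also partly confounded with lane, which may add to the hypoxia calls. At 0 h, 665 identifiers differed between hypoxia and normoxia, 286 higher and 379 lower, and 514 of them by at least 2-fold. The test took the libraries as independent, though same-numbered libraries within an oxygen condition deviated together. Its p-values for all 3 hypoxia comparisons may therefore be too small. The first-ranked identifier, uc007tbv.2, was at 0.400 CPM ± 0.353 (SD, n = 3) in normoxia, from 1 to 4 counts per library, and at 22.3 CPM ± 3.52 (SD, n = 3) in hypoxia, a log2 fold change of 5.99 (SE 0.49, edgeR adjusted p = 2.19e-06). The identifier uc008jfl.1 went the other way, from 13.3 CPM ± 4.20 (SD, n = 3) in normoxia to 0.916 CPM ± 0.304 (SD, n = 3) in hypoxia, a log2 fold change of -3.79 (SE 0.45, edgeR adjusted p = 0.000136). Both differed in the stated direction in 3 of 3 same-numbered pairs, which the rule for naming fixes by asking for no overlap. The number called was 420 without normoxia 0 h replicate 1, 356 without normoxia 0 h replicate 2, 371 without hypoxia 0 h replicate 1 and 398 without hypoxia 0 h replicate 2, and 310 with only the compared groups in the fit. It was 1473 with the replicate block, 2452 with the replicate block and lane (1233 higher, 1219 lower), and 1766 with the reads outside annotated features as a covariate chosen after seeing the data (902 higher, 864 lower). With no filter on low counts 398 were higher and 359 lower, so the excess of lower calls depended on the setting.

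At 12 h without treatment, 741 identifiers differed, 261 higher and 480 lower in hypoxia, 539 of them by at least 2-fold. The log2 fold change of uc007tbv.2 was 5.05 (SE 0.48, edgeR adjusted p = 1.38e-05) and that of uc008jfl.1 was -2.61 (SE 0.42, edgeR adjusted p = 0.00157). Of the identifiers called at 0 h and at 12 h, 161 were higher and 265 lower in both, against 5.56 and 13.5 for independent lists, and 0 were called in opposite directions. Among the 980 called at either time, 99.1% had the same sign at both. The correlation of log2 fold changes across identifiers was 0.687, with a covariance of 0.302, of which 0.0697 would come from deviations shared by same-numbered libraries. It was 0.270 with DESeq2 and 0.210 with no filter on low counts, where low-count identifiers were taken in too. Leaving out any 1 library other than hypoxia replicate 3 gave 395 to 483 calls, and without hypoxia 12 h untreated replicate 3 there were 498. With only the compared groups in the fit, 300 were called. The replicate block gave 1723 (706 higher, 1017 lower), the block with lane 1774 (829 higher, 945 lower), and the covariate chosen after seeing the data 2765, of which more were higher (1445) than lower (1320). No block with lane held libraries of both groups compared here, so the 1774 calls rest on indirect comparisons.

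**Figure D3:**
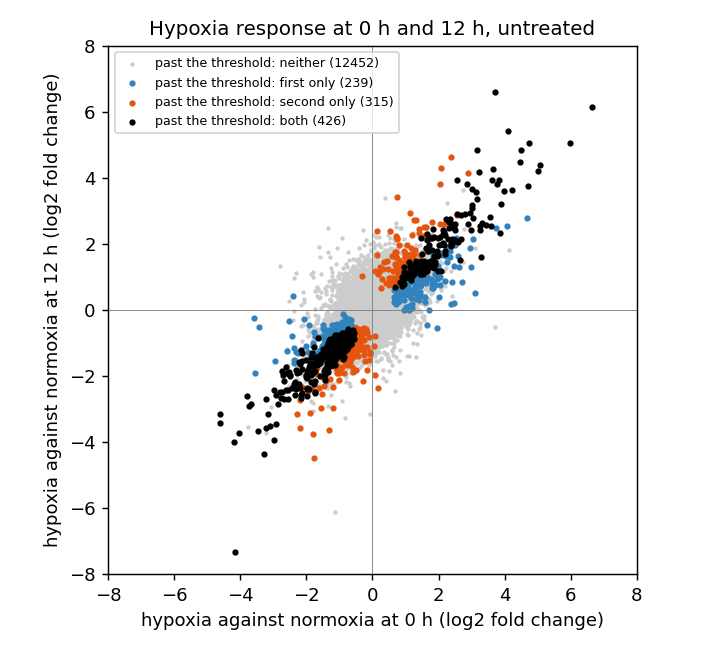
Log2 fold change of hypoxia against normoxia at 0 h (x axis) and at 12 h untreated (y axis) for 13432 identifiers, each a point coloured by the comparison in which it passed the test. The 426 identifiers past the threshold at both times lie in the quadrants where both changes have the same sign.

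With IL-6 present at 12 h, 389 identifiers differed between hypoxia and normoxia, 180 higher and 209 lower, 330 of them by at least 2-fold. The identifier uc007tbv.2 had a log2 fold change of 5.82 (SE 0.52, edgeR adjusted p = 8.55e-06) and uc008jfl.1 of -1.76 (SE 0.34, edgeR adjusted p = 0.00791). IL-6 raised uc008jfl.1 in both oxygen conditions, from 11.3 CPM ± 4.17 (SD, n = 3) to 52.4 CPM ± 6.01 (SD, n = 3) in normoxia and from 1.93 CPM ± 1.1 (SD, n = 3) to 15.3 CPM ± 6.31 (SD, n = 3) in hypoxia, with edgeR adjusted p of 0.00562 and 0.00111. In all 3 hypoxia comparisons, 112 identifiers were higher and 146 lower, and 1030 were called in at least 1. Deviations shared by same-numbered libraries would add to that overlap, and their part in it was not computed. Leaving out any 1 library other than hypoxia 12 h IL-6 replicate 3 gave 183 to 246 calls, and the call of uc008jfl.1 was lost without hypoxia 12 h IL-6 replicate 2 (adjusted p = 0.063). Without hypoxia replicate 3 in all 3 groups, an alternative chosen after seeing the data, 626 were called, and with only the compared groups in the fit 139, 72 higher and 67 lower. DESeq2 called 654, the replicate block 992, the block with lane 1945 (1025 higher, 920 lower), and the covariate chosen after seeing the data 1063. With no filter on low counts 281 were higher and 246 lower.

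**Figure D4:**
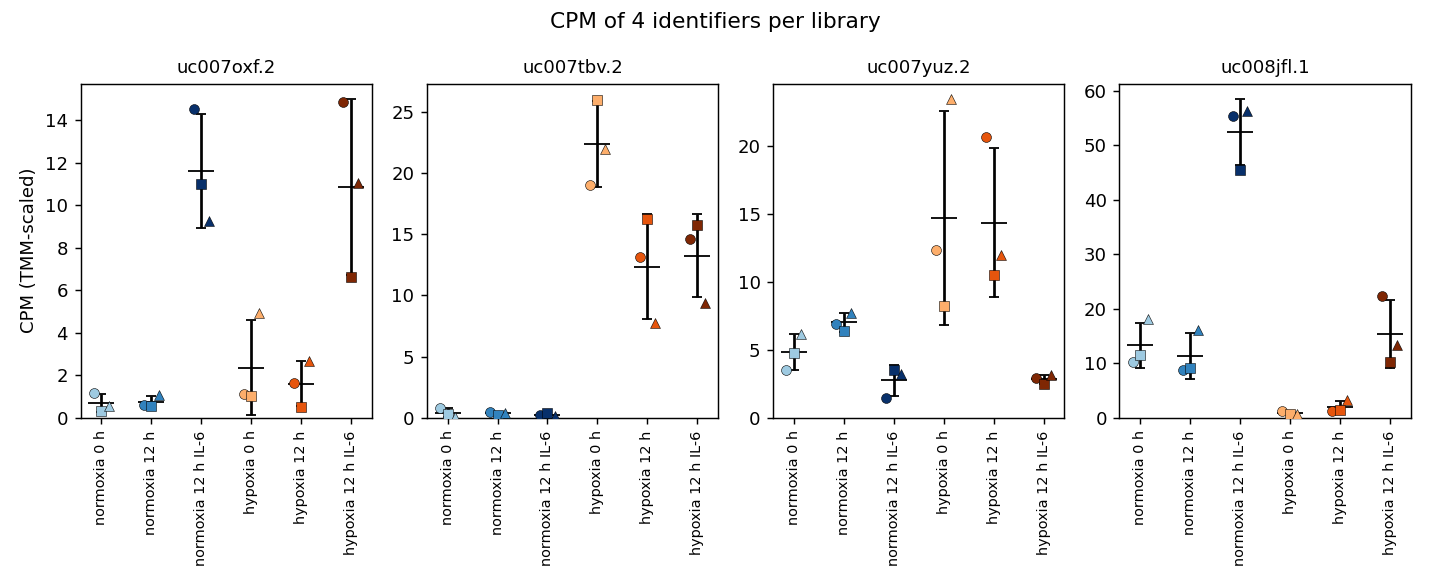
CPM (y axis, TMM-scaled) of 4 identifiers in each group (x axis); points are libraries, marker shape gives the replicate number, and bars are the mean and SD of 3 libraries. The identifier uc007tbv.2 is at most 0.787 CPM in the 9 normoxia libraries and at least 7.72 CPM in the 9 hypoxia libraries.

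Between 0 h and 12 h without treatment, 1 identifier was called in normoxia and it fell, with a log2 fold change of -4.37, from 2.84 CPM ± 0.324 (SD, n = 3) to 0.125 CPM ± 0.113 (SD, n = 3). It lies under the mean of 5 CPM that the rule for naming asks for and was picked out after its values were seen. It was not called when any 1 of the 6 libraries was left out, nor with only the compared groups in the fit. In normoxia 108 identifiers were at an unadjusted p under 0.05 by edgeR, where 671.6 would be expected by chance, or 776 with the replicate block within oxygen. In hypoxia 0 identifiers were called by edgeR and 2 by DESeq2, with 625 at an unadjusted p under 0.05 by edgeR, or 2052 with the replicate block within oxygen. With the replicate block within oxygen, 19 identifiers were called in normoxia, 7 higher and 12 lower at 12 h (10 higher and 2 lower without replicate 2, with 2 shared), and 254 in hypoxia, 76 higher and 178 lower. The time by oxygen interaction called 0 by edgeR and 0 by DESeq2, with 260 at an unadjusted p under 0.05 by edgeR, or 1347 with the block. With the block it called 15, all with a lower 12 h change in hypoxia. That single direction was lost without replicate 3, with 33 higher and 34 lower and 11 of the 15 shared. Leaving out replicate 1, 2 or 3 in every group gave blocked counts of 8, 12 and 63 for normoxia and 1, 5 and 67 for the interaction, and in hypoxia 17 without replicate 1 and 95 without replicate 2. The replicate block fixed beforehand gave 1 in normoxia and 0 in hypoxia, and with lane 3 and 47. Across identifiers, the time changes in the 2 oxygen conditions had a correlation of 0.0899, which was 0.0298 without replicate 3. It was 0.0330 with DESeq2 and 0.0269 with no filter on low counts, where low-count identifiers were taken in too.

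**Figure D5:**
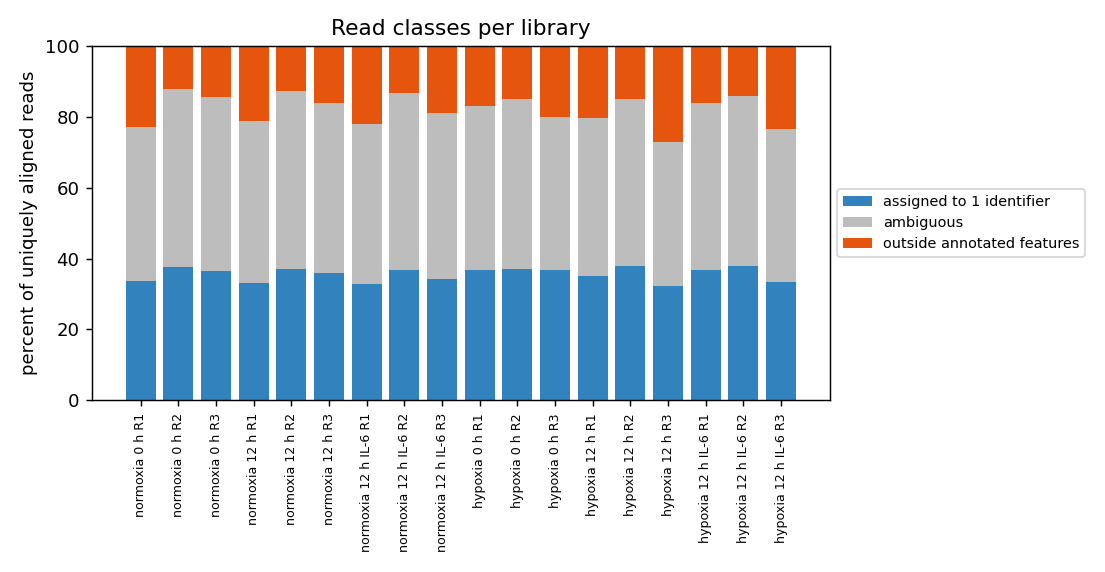
Percent of uniquely aligned reads (y axis) in each of the 18 libraries (x axis, R1 to R3 are replicate numbers) that were assigned to 1 identifier, ambiguous, or outside annotated features. The share outside annotated features runs from 12.1% to 27.1%.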

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

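In this part the replicate block within oxygen, the comparison of read classes between paired libraries and the tests of lane, of the second component and of depth for the IL-6 counts were chosen after the results were seen, as were the split counts for the 3 comparisons with 0 calls.

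The IL-6 response differed between hypoxia and normoxia for 6 identifiers, and the change from 0 h to 12 h for 15 identifiers, by interaction tests in edgeR with the replicate block within oxygen; without a block both tests called 0, with the replicate block across oxygen conditions 0 and 0, and with that block and lane 0 and 1. Leaving out 1 replicate number gave 0 to 4 and 1 to 67 calls. The share of reads outside annotated features rose with IL-6 in 3 of 3 normoxia pairs, by a mean of 1.52 percentage points ± 1.27 (SD, n = 3), and was lower in 3 of 3 hypoxia pairs, with a mean change of -2.93 ± 1.93 (SD, n = 3), a difference of -4.45 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.5 over 10 such tests). The ambiguous share moved the other way in every pair, with a difference of 2.86 percentage points (two-sided exact permutation p = 0.1, adjusted p = 0.5). Both measures were flagged because every normoxia pair moved opposite to every hypoxia pair. That fixes the permutation p-value in advance, so it decides nothing. Both are shares of the same uniquely aligned reads, so the ambiguous share is not a separate result.

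The hypoxia libraries of replicate 3 stood apart from replicates 1 and 2, at a median distance 2.14 times that between those 2, against 0.904 in normoxia. Lower depth does not account for all of it, since the ratio was still 1.62 after every library was thinned to the shallowest total. Nor does the share of reads outside annotated features as fitted in normoxia, since removing those slopes left a ratio of 2.07. The top 10 identifiers held a mean of 24.4% of assigned counts in hypoxia replicate 3, against 15.1% and 14.7% in replicates 1 and 2. Reads aligned to several places, per assigned read, averaged 1.14 against 3.38 and 3.04. In normoxia that ratio was also lowest in replicate 3, at 1.38 against 3.27 and 2.76. Neither measure was tested as a cause. All 3 libraries of lane 8 are hypoxia replicate 3, so lane and replicate number cannot be told apart. No biological explanation was tested.

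IL-6 was associated with more calls in hypoxia (56) than in normoxia (27), and the interaction without the block called 0. The order turned with only the compared groups in the fit, with 4 calls in hypoxia and 16 in normoxia. Without 12 h IL-6 replicate 1 of the condition tested, hypoxia gave 21 and normoxia 22. Without 12 h untreated replicate 1 of that condition, hypoxia gave 25 and normoxia 17. Hypoxia stayed ahead with DESeq2 (126 against 73) and with the replicate block within oxygen (729 against 398). The hypoxia libraries held 0.816 times the mean assigned total of the normoxia libraries, but within hypoxia the IL-6 libraries were deeper than the untreated ones in 3 of 3 pairs, with means of 8043653 and 4861150. Depth is argued against only as the whole cause: with every library thinned to the shallowest total, hypoxia had more calls in 10 of 10 thinnings, 28 to 35 against 19 to 25, and the median difference was 10.5. The median variance of the paired differences was 1.47 times as large in hypoxia. This cannot decide whether a smaller spread gave more calls, since the unpaired test shared each identifier's spread over all 6 groups. Its median SE was 0.390 for IL-6 in normoxia and 0.399 for IL-6 in hypoxia. A larger response to IL-6 in hypoxia, the biological explanation, stays open: over the 24 identifiers called in both, the median paired log2 change was 2.27 ± 0.26 (SD, n = 3) in normoxia and 2.26 ± 0.29 (SD, n = 3) in hypoxia, a difference of -0.0118 (two-sided exact permutation p = 0.9), and these identifiers were picked for being called in both.

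The second principal component may follow the share of reads outside annotated features. Over the 6 combinations of oxygen and replicate number, Pearson's r was 0.659 (exact permutation p = 0.178, adjusted p = 0.356 over 2 components) and Spearman's rho 0.60 (exact permutation p = 0.242). Without the 2 combinations farthest from the median r was 0.178, so the relation rests on those, and it cannot be tested within 1 oxygen condition of 3.

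Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In 1 of 10 splits, the real one, as many identifiers were called for IL-6 in normoxia (27, highest other 0), IL-6 in hypoxia (56, highest other 0), hypoxia at 0 h (665, highest other 0), at 12 h untreated (741, highest other 0) and at 12 h with IL-6 (389, highest other 0), and 12 h against 0 h in normoxia (1, highest other 0). Every other split puts libraries of both groups on both sides, so real changes add to its spread and a highest other of 0 decides little. For 12 h against 0 h in hypoxia the real count of 0 was matched by 10 of 10 splits, which decides nothing. Among the 4 splits that part all 3 pairs, the blocked counts of 398, 729, 19 and 254 for IL-6 in normoxia, IL-6 in hypoxia, time in normoxia and time in hypoxia stood against a highest other of 0. These 4 splits are also too few for a share under 0.05. The others reverse whole pairs, so real changes add to their spread and a highest other of 0 decides little. For the interactions, all 100 of 100 drawn splits gave as many as the real 0, which decides nothing; the highest others were 2111 and 1862 for IL-6 by oxygen and 1 for time by oxygen. Splits with so many calls point to a structure of the samples, and which one was not tested.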

How the results depend on the processing

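The replicate block within oxygen, the removal of hypoxia replicate 3, the covariate, the runs leaving out a replicate number and all agreement alternatives except the called identifiers were chosen after seeing the data; the others were fixed before. Values are in the order IL-6 in normoxia, IL-6 in hypoxia, IL-6 by oxygen, hypoxia at 0 h, 12 h and 12 h with IL-6, time in normoxia, time in hypoxia and time by oxygen, and counts within 1.5 times the reported one are left out; except where the construction is named, the cause was not tested. RLE size factors kept all 9 counts within that range.

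With no filter on low counts, which tests more identifiers, counts were 55 and 113 for IL-6, 1 for IL-6 by oxygen, 9 for time in hypoxia and 3 for time by oxygen. DESeq2 gave 73 and 126 for IL-6, 654 for hypoxia with IL-6, and 2 and 2 for time. The replicate block gave 99 and 169 for IL-6 and 1473, 1723 and 992 for hypoxia, where pairing by number stays open. The replicate block with lane gave 181 and 418 for IL-6, 2452, 1774 and 1945 for hypoxia, 3 and 47 for time and 1 for time by oxygen. Few of its blocks held both oxygen conditions, so its hypoxia counts rest largely on indirect comparisons. The replicate block within oxygen gave 398, 729 and 6 for IL-6 and its interaction and 19, 254 and 15 for time and its interaction. With only the compared groups, which leaves fewer samples, counts were 16 and 4 for IL-6, 310, 300 and 139 for hypoxia and 0 for time in normoxia. For hypoxia that fit also takes no same-numbered libraries of the same oxygen condition as independent. Without hypoxia replicate 3 in all 3 groups, 36 were called for IL-6 in hypoxia and 626 for hypoxia with IL-6. With the log ratio of reads outside features as a covariate, counts were 68 and 217 for IL-6, 1766, 2765 and 1063 for hypoxia and 5 for time in hypoxia.

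Leaving out 1 library gave 6 to 25 and 21 to 56 calls for IL-6, 356 to 656, 395 to 498 and 183 to 351 for hypoxia, and 0 to 0 for time in normoxia. With the block, leaving out 1 replicate number gave 161 to 368 and 198 to 680 for IL-6, 0 to 4 for IL-6 by oxygen, 8 to 63 and 17 to 257 for time, and 1 to 67 for time by oxygen.

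The correlation between oxygen conditions for IL-6 was 0.886 over identifiers called in either, 0.0629 with no filter, 0.0788 with DESeq2 and 0.228 to 0.301 leaving out 1 replicate number. Between 0 h and 12 h for hypoxia it was 0.916, 0.210, 0.270 and 0.557 to 0.677, and 0.763 under the replicate block with lane. For time it was 0.0269 with no filter, 0.0330 with DESeq2 and 0.0298 to 0.0820. The no-filter and DESeq2 correlations took in every identifier with at least 1 count, so they are not over the filtered identifiers alone. Of 142 alternative values for the 4 printed identifiers, 130 kept their direction and side of the threshold, 11 lost the call, 1 gained it and 0 reversed. Gene list alternatives were not run. A count of 0 allows a level of up to 0.971 CPM in the shallowest library, for counting error only; the simulations changed identifiers with a mean of at least 20 counts and did not test depth.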

Other observations

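The test of IL-6-raised identifiers in hypoxia and the comparison of read classes between paired libraries were both made on these data, and the second was chosen after the read classes were seen.

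The 27 identifiers raised by IL-6 in normoxia were tested for a shared shift in hypoxia against normoxia at 0 h, as would be seen if hypoxia alone raised them. The camera test gave p = 0.65 with a preset correlation of 0.01 and p = 0.823 with an estimated correlation of 0.152. The median log2 fold change was 0.01 and the mean -0.04, with 14 of the 27 higher in hypoxia, 2 called higher and 1 called lower, so the test decides neither way.

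Reads aligned to several places, per assigned read, were fewer with IL-6 than without in 6 of 6 same-numbered pairs. The mean change was -0.809 ± 0.539 (SD, n = 6 pairs). A two-sided exact permutation test by sign flips, which took the 6 pairs as independent, gave p = 0.0313 (adjusted p = 0.312 over 10 tests). The result fails the correction. In normoxia and hypoxia the changes were -1.37 and -1.55 for replicate 1 and -0.202 and -0.375 for replicate 2. For replicate 3 they were -0.637 and -0.720. The changes thus went with the replicate number. Pairing across oxygen stays open, so the 6 pairs cannot be taken as independent and this p-value decides nothing. Over all 18 libraries the ratio ran from 0.764 to 4.18.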
